A study of Sus scrofa with 8 samples.

How the data were processed

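H3K27ac ChIP-seq of pig pgEpiSC and pEF was taken from 4 deposited island lists, 1 for each H3K27ac library, which were the pgEpiSC libraries numbered 1 and 4 and the pEF libraries numbered 1 and 2. The 4 input libraries had no lists of their own, and their reads appear inside the lists of the matching H3K27ac library. Per the labels, DNA was fragmented to about 200 to 500 bp and sequenced as 150 bp paired-end reads, at a mean of 121 M raw and 116 M high-quality reads per library. BWA 0.7.15, SAMtools 0.1.19 and SICER 1.1 are credited per the submitters' processing notes. The lists have no header, and their 8 columns match a SICER islands summary. The deposited count columns hold the ChIP reads and the input reads in each island, as whole numbers. The deposited p-value columns hold the p-value of each island against the input and the FDR derived from it. The deposited fold column is the ratio of ChIP reads to input reads scaled to library size, and its relation to the 2 counts was constant within each list. Islands were built from 200 bp windows, the smallest gap between islands was 800 bp, and the FDR reached 1.00 in all 4 lists, so no FDR limit had been applied to them. Islands held a median of 274, 307, 275 and 334 ChIP reads and at least 41, 45, 32 and 38, in the order pgEpiSC 1, pgEpiSC 4, pEF 1 and pEF 2. Duplicate removal and mapping filters were not given in the sources used here.

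The genome build was not named in the labels or the lists. Unplaced scaffold names began with a prefix of the current pig assembly for 196 names. Gene ends of the reference table lay in islands more often than places 20 kb away on 19 of 19 chromosomes. On these grounds that table was used. It gives no strand, so transcription starts could not be told from ends: windows of 2 kb on either side of both ends of a gene replaced the promoter windows planned before the data were examined. The genome sequence was not used here, so the planned motif comparison was not run, and the planned split into exons and introns was reduced to gene end, inside a gene and between genes. The 16298 protein-coding genes with a symbol on chromosomes 1 to 18 and X were analysed, and 384 of the 398 distinct listed genes matched; CTGF is the older symbol of CCN2.

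The design, the gene lists and the rule for naming genes were fixed at that time too. The 22 lists were core pluripotency factors, formative and primed epiblast, naive pluripotency, epithelial adhesion, mesendoderm and gastrulation, trophectoderm and amnion, primordial germ cell, fibroblast extracellular matrix, mesenchymal transcription factors, fibroblast surface and signalling, the AP-1, TEAD and YAP axis, smooth muscle and contractile, HOX genes, neural progenitor, endothelial, blood cell, skeletal muscle, chondrocyte and bone, and keratinocyte markers, negative regulators of the FGF, WNT and TGF-beta pathways, chromatin and DNA methylation enzymes, and housekeeping genes. The named genes were POU5F1, SOX2, NANOG, LIN28A, OTX2, SALL4, COL1A1, COL1A2, COL3A1, TWIST1, PRRX1 and THY1 whatever their result. Added to these were up to 4 members per list with the largest difference in acetylated length, the 10 genes per direction with the largest such difference among those with an end island in both libraries of 1 type only, the 5 gene-end regions per direction with the largest log2 fold change past the threshold in edgeR, and the genes nearest to the 5 highest stitched domains per type. The rule gave 133 genes.

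Islands of the 4 libraries that overlapped by at least 1 bp were merged into regions, and a region was assigned to a library that had an island in it. Similarity was the Jaccard index over base pairs, also after shifts along the chromosomes. The number of regions or genes specific to a type was set against the 2 crossed pairings of the libraries. Fisher's exact test, two-sided, was used for list membership among type-specific genes, with Benjamini-Hochberg adjustment over 44 tests, and for position at gene ends. Acetylated length per gene was tested by limma 3.58.1 with a trend on log2(kb + 1), with 2 residual degrees of freedom, and ChIP reads inside each library's islands, summed over regions called in all 4 libraries, by edgeR 4.0.16 (quasi-likelihood, TMM). The 609 genes with no island in any library stayed in that fit, and limma offset their variance of 0; on genes with a mean of at least 1 kb, 5794 were higher in pgEpiSC and 1962 in pEF. TMM factors were 1.08, 1.08, 0.939 and 0.909 in the same order of libraries, and the common dispersion was 0.0797. The adjusted p threshold was 0.05 throughout. Stitched domains joined distal islands within 12 kb, ranked by ChIP reads minus scaled input, and kept those past the point where the scaled curve has a slope of 1. R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

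The overlap functions were tested on simulated data in 1800 checks with 0 wrong, and the list test found all 10 planted lists and called 0 of 34 lists with nothing planted. With 100 simulated regions changed by 2-fold and 100 by 4-fold, edgeR recovered 9% and 81%, with 1 call among 20596 unchanged regions. That simulation changed far fewer regions than edgeR called in the data. It also did not model counting inside each library's own islands, so it cannot show false calls from that source. With 200 of the genes changed limma recovered 0% at either size, and with 6000 changed it recovered 42.2% at 2-fold and 71.3% at 4-fold, with 133 calls among 10298 unchanged genes.

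The alternatives set before the data were examined were islands at an FDR under 1e-10, equal island numbers per library, other overlap and merging rules, gene-end windows of 1 and 5 kb, flanks of 0 and 50 kb, a pseudocount of 0.2 kb, a filter on a mean of 1 kb, a background of genes with an end island in at least 1 library, DESeq2, library size alone, edgeR's filterByExpr, regions covered to 80% in every library, 3 changes to the stitching, and leaving out each library. Chosen after seeing the data were islands at an FDR under 0.01, islands of at least 2-fold enrichment, centring on the median gene without genes that had no island in any library, limma on the ratio of ChIP to scaled input, equal island numbers for the island counts and lists, and leaving out each library for the island counts, the Jaccard index, positions and lists.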

Results

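H3K27ac, an acetylation mark of histone H3 found at active promoters and enhancers, was profiled by ChIP-seq in 2 pig cell types. The pgEpiSC libraries came from pre-gastrulation epiblast stem cells, labelled as derived from the embryonic day 10 epiblast, and the pEF libraries from embryonic fibroblasts of day 30. The labels do not say whether libraries of a type share a line, animal or culture, and their X chromosome reads differed, as given at the end. Each type had 2 H3K27ac libraries, pgEpiSC 1 and 4 and pEF 1 and 2, and each of these 4 libraries had its own input. For each H3K27ac library there was a list of islands, which are stretches of the genome where ChIP reads cluster, with the ChIP and the input reads inside each. ChIP reads inside islands numbered 29679982 in pgEpiSC 1, 38230571 in pgEpiSC 4, 42444995 in pEF 1 and 46383051 in pEF 2. The whole depth of each library was not given in the sources used here. The comparison of pgEpiSC with pEF asks where active chromatin differs between an epiblast stem cell and a fibroblast, and every error below is an SD over n = 2 libraries unless stated otherwise.

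At the loci of the core pluripotency factors, pgEpiSC carried longer acetylated stretches. Acetylated length is the kb covered by islands in the gene body and 10 kb on either side, compared by limma on log2(kb + 1), so the pseudocount is 1 kb. The counts per list below stand against all 16298 genes tested, of which 5194 were higher in pgEpiSC and 1773 in pEF. POU5F1, which encodes OCT4, was covered over 25.6 ± 0.566 kb in pgEpiSC and 3.90 ± 0.424 kb in pEF (log2 fold change 2.45, adjusted p = 0.00489). SOX2, its partner in the pluripotency network, had 20.96 kb in both pgEpiSC libraries, which is the whole window, against 2.90 ± 0.141 kb. Its log2 fold change of 2.49 was thus capped by the window and its SD in pgEpiSC was fixed at 0, and at POU5F1 pgEpiSC 1 also filled the window. LIN28A, an inhibitor of let-7 processing, had 21.0 ± 0.849 kb against 4.30 ± 0.990 kb, and TRIM71, another heterochronic RNA-binding protein, had 86.2 ± 3.39 kb against 1.3 ± 0.141 kb. SALL4 and PRDM14, both transcription factors of pluripotent cells, had 38.4 ± 1.70 kb and 38.6 ± 1.99 kb in pgEpiSC and no island in either pEF library. Of the 15 members of the core pluripotency list, 10 were higher in pgEpiSC, 0 were higher in pEF and 5 did not pass, and adjusted over the list alone the number higher in pgEpiSC was again 10. Once each library was centred on its median gene, 10 were higher in pgEpiSC and 1 in pEF. NANOG did not pass, at 9.70 ± 4.10 kb against 3.90 ± 1.27 kb (adjusted p = 0.13), and the other 4 that did not pass were DPPA2, L1TD1, ZFP42 and DPPA5, picked out after their values were seen. With islands of at least 2-fold enrichment over input the log2 fold change at NANOG was -1.23 ± 0.90 (SE, adjusted p = 0.419).

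Genes of the formative and primed epiblast followed the same direction. OTX2, a regulator of the primed state, had 29.4 ± 0.141 kb in pgEpiSC and no island in pEF, and the de novo DNA methyltransferase genes DNMT3A and DNMT3B had 117 ± 5.52 kb against 12.4 ± 3.96 kb and 57.0 ± 0.283 kb against 9.64 ± 1.36 kb. Of 18 members, 13 were higher in pgEpiSC, 4 did not pass and FGF2, picked out after its values were seen, was higher in pEF. The counts were 13 and 1 adjusted over the list alone, and 10 and 2 once values were centred. Of 14 naive pluripotency genes, 5 were higher in pgEpiSC, 2 were higher in pEF and 7 did not pass, with the same 5 and 2 adjusted over the list alone, but 1 and 4 with islands of at least 2-fold enrichment over input. ESRRB, an orphan nuclear receptor, had 97.1 ± 2.35 kb against 2.40 ± 0.0 kb, while TBX3 had no island in pgEpiSC and 18.8 ± 1.13 kb in pEF. The other members past the threshold were KLF5, TFAP2C, DPPA3 and FGF4 in pgEpiSC and KLF2 in pEF, the last 3 named after their values were seen.

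The epithelial adhesion list was higher in pgEpiSC at 21 of its 24 loci, higher in pEF at 0, and not past the threshold at 3. Adjusted over the list alone 22 were higher in pgEpiSC, and 18 once values were centred, with 0 higher in pEF. CDH1, which encodes E-cadherin, had 65.7 ± 5.51 kb against 13.0 ± 5.37 kb (log2 fold change 2.30, adjusted p = 0.0205). GRHL2 and ST14, an epithelial transcription factor and a membrane serine protease, had 47.0 ± 3.68 kb and 37.7 ± 3.25 kb in pgEpiSC and no island in pEF, and GRHL3 had 50.6 ± 0.566 kb against 0.600 ± 0.849 kb. Mesendoderm and gastrulation genes were higher in pgEpiSC at 6 of 14 loci and in pEF at 0, with 8 not past the threshold and 7 higher in pgEpiSC adjusted over the list alone. WNT3, a signal of primitive streak formation, had 69.9 ± 1.62 kb against 2.80 ± 1.98 kb. FOXA2 and CER1 had 21.4 ± 1.84 kb and 18.3 ± 1.56 kb and no island in pEF. With islands of at least 2-fold enrichment 3 members were higher in pgEpiSC and FOXA2 did not pass (log2 fold change 1.69 ± 1.40, SE, adjusted p = 0.453). The primordial germ cell list had 5 of 9 members higher in pgEpiSC, namely KIT, TFAP2C, DAZL, PIWIL2 and DND1, and PRDM1 higher in pEF, with 3 not past the threshold. Adjusted over the list alone the counts were 6 and 1, and with islands of at least 2-fold enrichment they were 0 and 1. KIT, a receptor tyrosine kinase, had 42.0 ± 1.13 kb against 2.70 ± 1.56 kb. DND1 and PRDM1 were named after their values were seen.

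Fibroblast loci showed the opposite direction, and the HOX genes the most complete difference. Of 36 measured HOX genes, which set position along the body axis, 34 were higher in pEF, 0 were higher in pgEpiSC, and HOXB13 and HOXC12 did not pass. Adjusted over the list alone the count was also 34. HOXA3, HOXC6, HOXD9 and HOXA10 had 46.7 ± 14.1 kb, 32.3 ± 0.160 kb, 29.0 ± 4.67 kb and 28.3 ± 0.229 kb in pEF and no island in either pgEpiSC library. HOX genes lie side by side in clusters, and neighbours share islands, so these loci were not independent of each other.

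Extracellular matrix genes were higher in pEF at 14 of 26 loci, higher in pgEpiSC at 2 (FBLN1 and MFAP5, named after their values were seen) and not past the threshold at 10. The counts in pEF and pgEpiSC were 15 and 2 adjusted over the list alone. COL1A1, encoding a chain of type I collagen, had 8.80 ± 1.26 kb in pgEpiSC and 38.1 kb in both pEF libraries, where it filled the window, so its log2 fold change of -2.0 was capped, and COL1A2 and COL3A1 had no island in pgEpiSC and 49.4 ± 0.990 kb and 52.2 ± 2.69 kb in pEF. FBN1, encoding the microfibril protein fibrillin, had 22.1 ± 0.990 kb against 239.9 ± 10.04 kb, and FN1, encoding fibronectin, had 10.7 ± 1.84 kb against 86.8 ± 6.83 kb. COL12A1 did not pass, at 5.10 ± 7.21 kb against 103 ± 26.4 kb (adjusted p = 0.0746). Of 35 mesenchymal transcription factors, 20 were higher in pEF, 4 were higher in pgEpiSC and 11 did not pass, with the same 20 and 4 adjusted over the list alone. TWIST1, an inducer of the mesenchymal state, had no island in pgEpiSC and 17.0 ± 0.0636 kb in pEF, and RUNX1 had 28.3 ± 8.32 kb against 162 ± 9.33 kb. The 4 higher in pgEpiSC were NFIB, TCF12, ZEB2 and ALX4, the last 2 named after their values were seen. NFIB had 120 ± 10.4 kb against 29.0 ± 12.4 kb, and TCF12 no longer passed once values were centred (adjusted p = 0.379). PRRX1 did not pass, at 28.5 ± 17.1 kb against 78.1 ± 0.367 kb (adjusted p = 0.0957). Once values were centred PRRX1 and COL12A1 passed toward pEF (adjusted p = 0.0193 and 0.0206). With islands of at least 2-fold enrichment COL12A1 passed (adjusted p = 0.00715) and PRRX1 did not (adjusted p = 0.158).

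Among fibroblast surface and signalling genes, 11 of 24 were higher in pEF, 3 were higher in pgEpiSC and 10 did not pass. Adjusted over the list alone the counts were 13 and 4. CD44, a hyaluronan receptor, had 20.3 ± 1.56 kb in pgEpiSC and 94.7 ± 13.9 kb in pEF, and NRP1 had 11.7 ± 5.23 kb against 80.96 ± 23.4 kb. The 3 higher in pgEpiSC, named after their values were seen, were ENG, MME and CXCL12. THY1 did not pass, at 8.63 ± 4.76 kb against 13.4 ± 2.69 kb (adjusted p = 0.337), but did with islands of at least 2-fold enrichment (log2 fold change -3.83, adjusted p = 0.00892). The AP-1, TEAD and YAP list had 4 of 17 members higher in pEF (WWTR1, CTGF, ANKRD1 and AMOTL2), 2 higher in pgEpiSC (TEAD4 and TEAD2) and 11 not past the threshold, with 4 and 2 adjusted over the list alone. WWTR1, which encodes the coactivator TAZ, had 60.1 ± 2.69 kb against 92.4 ± 3.39 kb. The smooth muscle and contractile list had 4 of 14 higher in pEF (CALD1, TPM1, ACTG2 and ACTA2), 2 higher in pgEpiSC (MYL9 and TPM2) and 8 not past the threshold, with 4 and 2 adjusted over the list alone. CALD1, an actin-binding regulator, had 90.5 ± 5.52 kb against 229 ± 0.174 kb. Once values were centred the counts in pEF and pgEpiSC were 10 and 2 for the AP-1, TEAD and YAP list and 10 and 0 for the contractile list. CTGF, ANKRD1, AMOTL2, TEAD2, ACTA2, MYL9 and TPM2 were named after their values were seen.

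Lists for cell types that neither label names gave mixed results. Chondrocyte and bone markers were higher in pgEpiSC at 7 of 13 loci, blood cell markers at 6 of 14, skeletal muscle markers at 6 of 13, endothelial markers at 5 of 13 and keratinocyte markers at 5 of 11. In the same order 0, 2, 1, 2 and 1 members were higher in pEF and 6, 6, 6, 6 and 5 did not pass. The counts adjusted over the list alone were 7 and 1, 6 and 2, 6 and 1, 5 and 2, and 7 and 1. With islands of at least 2-fold enrichment they were 0 and 2, 1 and 2, 0 and 4, 0 and 4, and 1 and 1, so under that filter the excess in pgEpiSC was kept in none of these 5 lists. Over all genes the counts turned too, from 5194 and 1773 to 1150 and 2692, so neither the direction of the excess nor its loss was particular to these lists. No test set these list counts against those over all genes. Once values were centred the list counts were 6 and 1, 5 and 2, 5 and 2, 3 and 3, and 3 and 1. Whether the excess stayed thus depended on the setting. SOX5, a cartilage transcription factor, had 181 ± 47.0 kb in pgEpiSC against 37.5 ± 0.141 kb in pEF. LCP1, an actin bundler of leukocytes, had 43.7 ± 0.990 kb and no island in pEF, and LAMB3, a laminin chain of epithelial basement membrane, had 24.6 ± 2.26 kb and no island in pEF. ERG, an ETS factor of endothelium, was higher in pEF, at 98.8 ± 12.1 kb against 20.4 ± 2.83 kb. Trophectoderm and amnion genes were higher in pEF at 3 of 13 loci (GATA3, PTGS2 and HAND1), higher in pgEpiSC at 0, and not past the threshold at 10, with 2 and 0 adjusted over the list alone. Neural progenitor markers were higher in pEF at 3 of 13 loci (SIX3, FABP7 and NKX2-2), higher in pgEpiSC at HES5 and not past the threshold at 9, with 3 and 1 adjusted over the list alone. Once values were centred, 7 members of each of these 2 lists were higher in pEF. HAND1, FABP7 and NKX2-2 were named after their values were seen.

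Of 20 negative regulators of the FGF, WNT and TGF-beta pathways, 7 were higher in pgEpiSC, SKIL was higher in pEF and 12 did not pass, with 6 and 1 adjusted over the list alone. The balance turned to 4 and 5 once values were centred and to 3 and 4 with islands of at least 2-fold enrichment. AXIN2, a feedback inhibitor of WNT signalling, had 38.4 ± 4.74 kb against 8.90 ± 0.424 kb. Chromatin and DNA methylation enzymes were higher in pgEpiSC at 8 of 19 loci and in pEF at 0, with 11 not past the threshold and the same 8 adjusted over the list alone, but 7 and 3 once centred and 3 and 2 with islands of at least 2-fold enrichment. CHD7, a chromatin remodeller, had 115 ± 13.8 kb against 4.0 ± 1.13 kb. Housekeeping genes were not past the threshold at 12 of 16 loci. RPLP0, RPL13A and HSP90AB1 were higher in pgEpiSC and B2M in pEF, with 2 and 1 adjusted over the list alone. None of the 3 higher in pgEpiSC passed once values were centred, when 5 members were higher in pEF. SKIL and B2M were named after their values were seen.

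**Figure D1:**
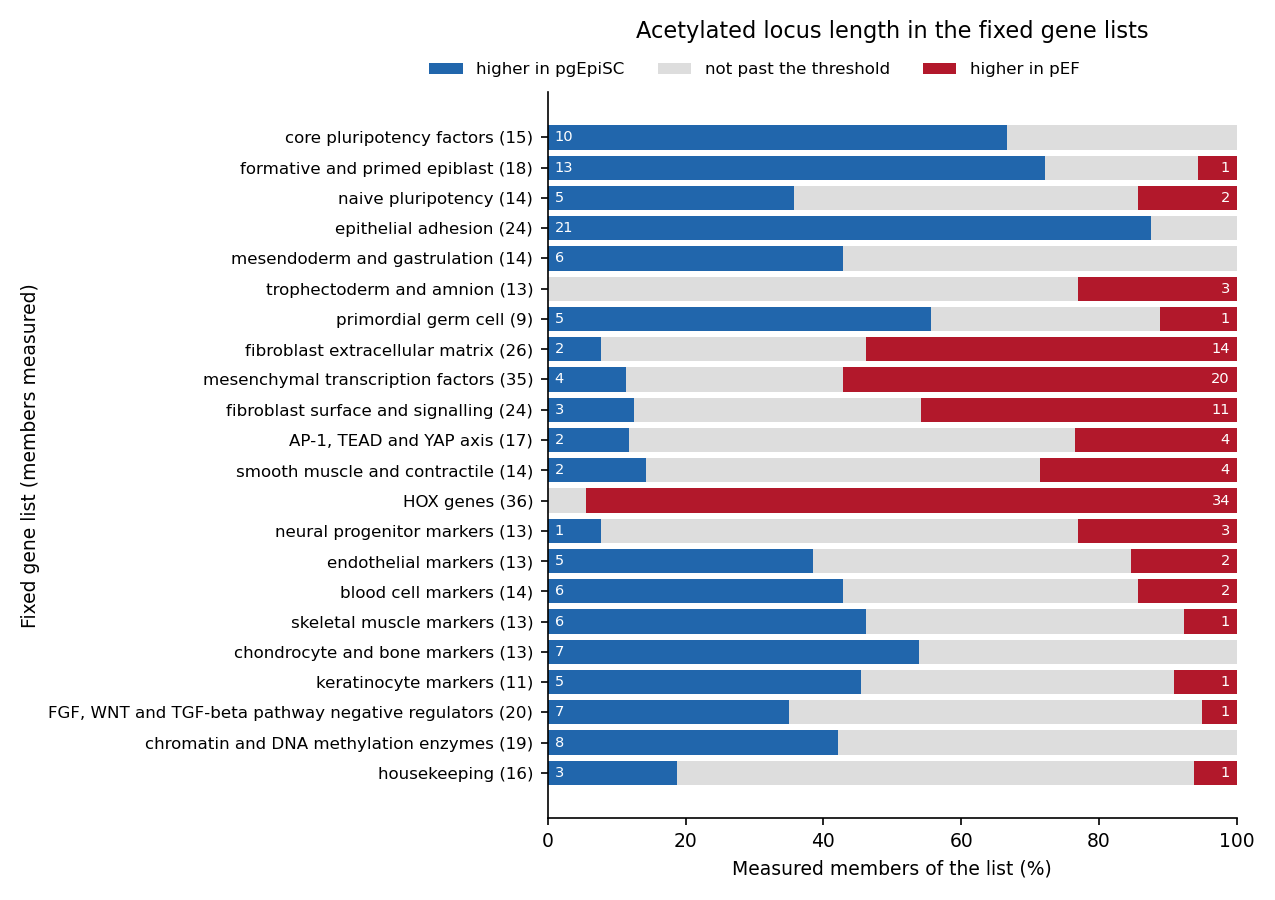
Share of measured members of each fixed gene list (x axis, %; number measured in brackets) with a longer acetylated locus in pgEpiSC (blue), in pEF (red) or not past the limma threshold (grey), with the counts printed in the bars. HOX genes had 34 of 36 members higher in pEF and epithelial adhesion genes 21 of 24 higher in pgEpiSC. Once values were centred these counts were 34 and 18. Housekeeping genes went from 3 higher in pgEpiSC and 1 in pEF to 0 and 5.

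**Figure D2:**
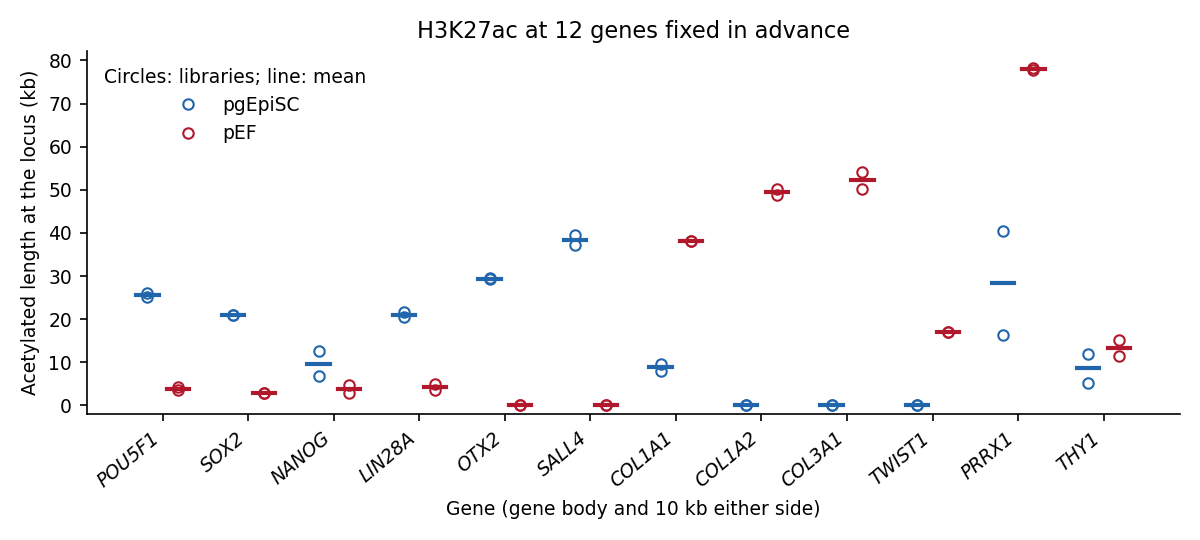
Acetylated length at the locus (kb, y axis) of 12 genes chosen before the data were examined, with circles for the 2 libraries of each cell type and lines for their means. COL1A2, COL3A1 and TWIST1 had no island in pgEpiSC, and OTX2 and SALL4 had none in pEF.

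Over all 16298 protein-coding genes tested, limma placed 5194 higher in pgEpiSC and 1773 higher in pEF, while 9331 did not pass. The median gene was 0.46 higher in pgEpiSC on the log2 scale, so the counts were repeated with each library centred on its median gene, over the 15689 genes with an island in at least 1 library. Centring lowered every log2 fold change by 0.63 and gave 3583 genes higher in pgEpiSC and 3852 higher in pEF, with 5301 past the threshold in the same direction in both fits. The median log2 fold change of 5 lists changed sign on centring, from 0.48 to -0.14 for naive pluripotency, from 0.07 to -0.57 for the AP-1, TEAD and YAP axis, from 0.45 to -0.18 for the negative regulators, from 0.52 to -0.11 for the chromatin enzymes and from 0.18 to -0.45 for housekeeping genes. With islands of at least 2-fold enrichment over input, 1150 genes were higher in pgEpiSC and 2692 in pEF, and of 2540 genes past the threshold in both fits 2312 kept their direction. That filter ended the call at SOX2 (log2 fold change 3.46 ± 0.84, SE, adjusted p = 0.0860), DNMT3B (1.76 ± 0.34, adjusted p = 0.0567), ESRRB (1.37 ± 2.01, adjusted p = 0.684) and all 4 germ cell genes named by the rule. Among genes given above it also ended the call at FN1 (-2.91) and TEAD4 (2.88), whose fold stayed near that of the main fit. The fold fell at SOX5 (1.56), NFIB (1.08), RPLP0 (0.96), LAMB3 (0.34) and RPL13A (0.32), which lost the call too. It turned without passing at TCF12 (-0.64) and HSP90AB1 (-0.15). The counts in pgEpiSC and pEF were then 8 and 0 for core pluripotency, 4 and 0 for formative, 13 and 0 for epithelial adhesion, 0 and 20 for matrix, 0 and 24 for mesenchymal and 0 and 31 for HOX genes. The filter left 28 of the 69 named genes higher in pgEpiSC and 39 of the 43 higher in pEF. Leaving out any library left 1686 to 2188 genes higher in pgEpiSC and 548 to 828 higher in pEF, on the assumption that the lone library of a type varies like the other type. These p-values, like those of edgeR, measure only the spread between these libraries. Those of Fisher's exact test below count genes or regions and hold no spread between libraries.

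Genes with an island at a gene end in both libraries of a type and in neither of the other type were counted next, the gene end being a window of 2 kb on either side of either end of the gene. There were 1191 such genes in pgEpiSC (7.31%) and 730 in pEF (4.48%), while 11049 genes had an end island in all 4 libraries and 1653 in none. Crossed pairings of a pgEpiSC with a pEF library gave 46 and 58 genes, against 1921 for the 2 cell types. The balance turned with islands at an FDR under 1e-10, to 864 genes in pgEpiSC and 1147 in pEF, and with islands of at least 2-fold enrichment, to 335 and 2013. The 10 with the largest gain in acetylated length in pgEpiSC included TENM4, ROBO1, GPM6A, NKAIN2 and ADGRL2. ADGRL2 had 439.9 ± 29.2 kb against 38.5 ± 5.66 kb. TMEM132D had 265 ± 13.3 kb and no island in pEF, and NAV2, SORCS2 and ARL15 were also among them. In pEF the 10 were DLC1, CPQ, PLA2G4A, SLC8A1, MICAL2, TNS1, WLS, ADAMTSL3, ITGA8 and CALD1. DLC1 had 283 ± 40.02 kb against 13.3 ± 0.990 kb, and ITGA8, an integrin of mesenchyme, had 147 ± 4.67 kb against 0.8 ± 1.13 kb. All 10 in pgEpiSC passed limma, as did 8 of the 10 in pEF, with CPQ (adjusted p = 0.0970) and SLC8A1 (adjusted p = 0.0534) not passing. The choice by kb favours long genes, and with islands of at least 2-fold enrichment 5 of the 10 in pgEpiSC and 7 of the 8 in pEF still passed, the exception being DLC1. Its log2 fold change grew from -4.31 ± 0.15 to -6.58 ± 1.26 (SE, adjusted p = 0.0564), so the call was lost to the larger SE.

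By Fisher's exact test, two-sided and adjusted over 44 tests of 22 lists, 7 lists held more pgEpiSC-only genes than expected from all genes and 4 held more pEF-only genes. In pgEpiSC these were epithelial adhesion (11 of 24 genes, odds ratio 10.8, adjusted p = 4.57e-06), primordial germ cell (5 of 9, odds ratio 15.9, adjusted p = 0.00179), chondrocyte and bone markers (6 of 13, odds ratio 10.9, adjusted p = 0.00179), core pluripotency (6 of 15, odds ratio 8.49, adjusted p = 0.00311), keratinocyte markers (5 of 11, odds ratio 10.6, adjusted p = 0.00413), blood cell markers (5 of 14, odds ratio 7.07, adjusted p = 0.0104) and the formative and primed epiblast (5 of 18, odds ratio 4.89, adjusted p = 0.0317). In pEF they were HOX genes (31 of 36, odds ratio 138, adjusted p = 1.11e-35), mesenchymal transcription factors (16 of 35, odds ratio 18.3, adjusted p = 8.99e-12), extracellular matrix (6 of 26, odds ratio 6.44, adjusted p = 0.00464) and trophectoderm and amnion (4 of 13, odds ratio 9.52, adjusted p = 0.0101). Mesendoderm and gastrulation genes did not pass (4 of 14 in pgEpiSC, adjusted p = 0.0576). The test takes genes, not libraries, as independent units. HOX genes share islands with their neighbours, so their p-value is too small. With islands of at least 2-fold enrichment, which left fewer pgEpiSC-only genes, the call ended for blood (odds ratio 3.67, adjusted p = 0.617), bone (odds ratio 3.98, adjusted p = 0.617) and keratinocyte (odds ratio 4.78, adjusted p = 0.599) genes. It also ended for trophectoderm genes (odds ratio 3.16, adjusted p = 0.209) among the pEF-only genes, which rose from 730 to 2013 under that filter. A gene-end window of 5 kb ended 7 of the 11 calls, including germ cell (adjusted p = 0.118) and matrix (adjusted p = 0.12) genes, and left core pluripotency, epithelial, mesenchymal and HOX genes. Islands at an FDR under 1e-10 ended the calls of formative, trophectoderm, blood, bone and keratinocyte genes. Equal island numbers ended those of formative and blood genes. Formative genes also lost their call without pgEpiSC 1, pgEpiSC 4 or pEF 1, with an adjusted p of up to 0.339 over their 11 alternatives.

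In the 20796 regions that all 4 libraries called, edgeR compared the ChIP reads that lay in each library's own islands inside the region, so reads between islands were not counted. The largest log2 fold changes toward pgEpiSC among regions at gene ends were at PPARGC1B and PDE6A on chromosome 2 from 150822601 to 150984200, at TRIM71 on chromosome 13 from 18754401 to 18841200, and at CLYBL, SOX2 and FGD4 with BICD1. In the PPARGC1B region, islands of pgEpiSC 1 and 4 covered 161.6 and 147.2 kb and held 13463 and 16484 ChIP reads, while those of pEF 1 and 2 covered 2.4 and 3.6 kb and held 145 and 202, a log2 fold change of 6.85 ± 0.27 (SE, adjusted p = 0.00131). The fold over input of the islands in the PPARGC1B region was 2.43 and 2.21 in pgEpiSC and 2.03 and 2.39 in pEF. Its counts thus differed mainly through island length. The SOX2 region on chromosome 13 from 119655601 to 119725200 had a log2 fold change of 6.31 ± 0.24 (SE, adjusted p = 0.00131). By limma on log2 of ChIP over scaled input, centred on each library's median, the log2 fold change was 1.46 at PPARGC1B, 1.34 at TRIM71, 1.25 at CLYBL and 2.36 at SOX2, all past the threshold, and 0.58 at FGD4 with BICD1, which did not pass. Without centring, where most regions were higher in pEF, it turned at TRIM71 (-0.041), CLYBL (-0.13) and FGD4 with BICD1 (-0.81). The largest toward pEF were at VIM, which encodes the intermediate filament protein vimentin, together with its neighbour TRDMT1 (chromosome 10 from 43494801 to 43529400, log2 fold change -6.63 ± 0.27, SE, adjusted p = 0.00131), and at ETS1, FAM213A, STK17B and CCL2. ETS1, an ETS-family transcription factor, had islands of 1.6 and 4.0 kb with 103 and 316 reads in pgEpiSC and of 79.6 and 84.4 kb with 19434 and 28034 reads in pEF. On the centred ratio to input VIM, ETS1 and FAM213A passed, and STK17B and CCL2 did not. Regions at the ends of core pluripotency genes were higher in pgEpiSC at 7 of 8 and those of extracellular matrix genes were higher in pEF at 16 of 22, with none of either list the other way, while with library size alone 14 matrix regions were higher in pEF and 1 in pgEpiSC. The other lists were not all as clear. Regions of epithelial adhesion genes were higher in pgEpiSC at 11 of 17 and in pEF at 1. For fibroblast surface genes these counts were 3 and 18 of 25, and for the AP-1, TEAD and YAP list 3 and 10 of 19. Negative regulators had 4 and 7 of 22 regions, against 7 and 1 loci by acetylated length. HOX genes had 1 such region, which did not pass. These list counts were not repeated on the ratio to input, so island length was not separated from enrichment in them. In all, 4705 regions were higher in pgEpiSC and 4854 in pEF, and with library size alone in place of TMM, which moved the median log2 fold change by 0.23, the counts were 5695 and 3842. Library size here was the sum of the reads counted in these regions, not sequencing depth. Both settings thus scale out a difference in total counts, and the near balance cannot show one. A count grows with the island length inside the region: of the regions higher in pgEpiSC 4525 also had more kb covered in both its libraries, and of those higher in pEF 3366 did. Where islands of every library covered at least 80% of the region, 77 and 67 passed, and on the ratio of ChIP to scaled input limma gave 44 and 16464, or 2562 and 1535 once centred. Without pgEpiSC 1 edgeR gave 2002 and 2090, and without pgEpiSC 4 it gave 1917 and 2041.

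Distal islands, those away from gene ends, were joined when within 12 kb and ranked by ChIP reads minus scaled input, and domains past the bend of the ranked curve were kept. The domains high in both pgEpiSC and in neither pEF library numbered 163, the reverse 312, and 38 were high in all 4 libraries. The top 5 of pgEpiSC lay in PTPRD, a receptor phosphatase gene (chromosome 1 from 212053201 to 212421800, 369 kb), in CLYBL, ARL15 and DLG2, and 2.26 kb from AKR1D1. The top 5 of pEF lay 282 kb from THBS1, which encodes thrombospondin (chromosome 1 from 132028001 to 132324800, 297 kb), 170 kb from KLF6, in NEDD9 and ADAM12, and 29.8 kb from SNX18. Domains of pgEpiSC had SALL4, PRDM14, OTX2, DNMT3A, EPCAM and GRHL2 as their nearest or overlapped listed genes, and domains of pEF had 8 matrix genes, among them FN1, FBN1 and TNC, and 6 mesenchymal factors, among them RUNX1 and SNAI1, but also NR5A2 of the naive list, PTPRC of the blood list, CDH5 and ERG of the endothelial list and SOX6 of the bone list. No test was made of these counts, and the number past the bend differed between libraries of the same type, at 260 and 766 in pgEpiSC and 447 and 1089 in pEF. Without pgEpiSC 1 the count of 163 became 586, and without pEF 1 the count of 312 became 902.

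Across the genome, pgEpiSC libraries had broader islands with less enrichment. The lists held 64620 and 74208 islands in pgEpiSC and 62261 and 57790 in pEF, covering 411 ± 3.85 Mb and 274 ± 1.15 Mb, with a median width of 4.50 ± 0.424 kb against 3.10 ± 0.141 kb. The median fold over input was 1.73 ± 0.0902 in pgEpiSC and 3.46 ± 0.00572 in pEF, and 32.4 ± 6.62% against 85.1 ± 0.682% of islands reached 2-fold. The number of islands turned at an FDR under 1e-10, to 46040 in pgEpiSC and 53491 in pEF, and at 2-fold enrichment, to 22286 and 51098. Over islands of at least 2-fold enrichment the direction of covered length turned too, to 163 ± 26.1 Mb in pgEpiSC and 247 ± 1.90 Mb in pEF. With 2 libraries against 2 the smallest two-sided exact permutation p is 0.333, so these differences were set only against the SD.

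**Figure D3:**
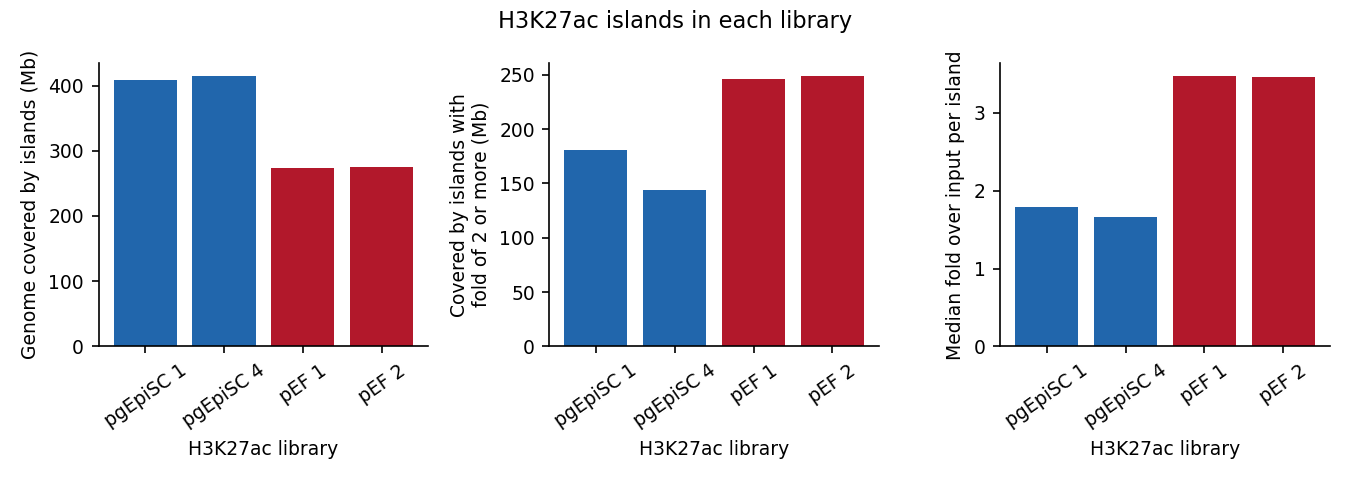
Genome covered by islands (Mb), genome covered by islands of at least 2-fold enrichment (Mb) and median fold over input per island in each of the 4 H3K27ac libraries. The pgEpiSC bars are higher in the left panel (408 and 414 Mb against 273 and 275 Mb) and lower in the others.

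Libraries of the same cell type shared more of their islands than libraries of different types. The Jaccard index over base pairs was 0.560 between the pgEpiSC libraries, 0.631 between the pEF libraries and 0.186 ± 0.00286 (SD over 4 pairs) between types. Merging all islands gave 102641 regions, of which 22527 were called in both pgEpiSC and neither pEF library, 18019 in both pEF and neither pgEpiSC library, and 20796 in all 4, while crossed pairings gave 804 and 865. The pEF-only regions were the larger class with islands at an FDR under 1e-10 (13697 in pgEpiSC and 19153 in pEF), with equal island numbers (18203 and 19021) with islands of at least 2-fold enrichment (3997 and 23536) and without pEF 2 (24023 and 25781). Without pgEpiSC 1 the count of 22527 became 34766.

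Regions called in all 4 libraries lay at gene ends far more often than regions of a single cell type. The share was 52.1% for common regions, 11.98% for pgEpiSC-only and 9.18% for pEF-only regions, against 21.9%, 13.6% and 10.7% after the regions were shifted along the chromosomes. Among regions 3 to 5 kb wide the shares were 67.0%, 9.97% and 7.40%. The pgEpiSC-only and pEF-only classes differed by an odds ratio of 1.35 (Fisher's exact test over regions, p = 1.60e-19), which was 0.991 (p = 0.806) for islands at an FDR under 1e-10 and 0.732 (p = 4.28e-09) for islands of at least 2-fold enrichment, so its direction was not settled. Without pgEpiSC 4 it was 1.06 (Fisher's exact p = 0.0674).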

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

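The islands at an FDR under 0.01, those of at least 2-fold enrichment, centring, limma on the ratio of ChIP to scaled input, equal island numbers for islands and lists, and leaving out libraries for islands, the Jaccard index, positions and lists were chosen after the results were seen; the other settings were not. No paired analysis was possible because only the number 1 is shared between the types and the labels do not say that equal numbers belong together. Limits include the 2 libraries per type, gene ends without strand, counts of reads inside islands alone and the lower enrichment of the pgEpiSC libraries, so that any setting that asks for stronger islands removes more from pgEpiSC. Of 196 comparisons of a value or count with an alternative 120 were the same, 73 moved, 1 weakened and 2 reversed. Counts of genes and regions were labelled the same within a fixed factor of the main value, so the same did not mean unchanged. At an FDR under 1e-10, for instance, genes longer in pgEpiSC fell from 5194 to 3606 and pgEpiSC-only genes from 1191 to 864, both labelled the same. For the 11 lists past the threshold 98 of 121 comparisons kept the call, and over all lists 455 of 484 kept their direction and side of the threshold, as did 1399 of 1727 for acetylated length at named genes and 83 of 90 for named regions. A change of sign was counted only where at least 1 of the 2 values passed the threshold. Core pluripotency, epithelial adhesion, mesenchymal factors and HOX genes kept their call under all 11 list alternatives, and germ cell and matrix genes under 10, the exception being the 5 kb window. Keratinocyte markers kept it under 8, blood, bone and trophectoderm genes under 7 and formative genes under 5. The motif comparison and its alternatives were not run, as the genome sequence was not used here. The cause was not tested for any change below.

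At an FDR under 1e-10 there were 46040 islands per library in pgEpiSC and 53491 in pEF, covering 318.9 and 258 Mb, the Jaccard index between types was 0.177, and 13697 regions were specific to pgEpiSC. Gene ends then held 11.7% of pEF-only and 59.7% of common regions, the odds ratio of gene-end position for pgEpiSC-only against pEF-only regions was 0.991, 1147 genes had end islands in pEF only, and 4 lists were over-represented in pgEpiSC. At an FDR under 0.01 covered length was 398.9 and 272 Mb and the share of common regions at gene ends 53.0%. With equal island numbers covered length was 366 and 269 Mb and the Jaccard index between types 0.182.

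With islands of at least 2-fold enrichment there were 22286 islands in pgEpiSC and 51098 in pEF, covering 163 and 247 Mb. The Jaccard index was 0.487 within pgEpiSC, 0.621 within pEF and 0.149 between types, and 3997 regions were specific to pgEpiSC. Gene ends held 10.9% of pgEpiSC-only, 14.3% of pEF-only and 73.6% of common regions, and the odds ratio of position turned to 0.732. Genes with end islands in 1 type only numbered 335 in pgEpiSC and 2013 in pEF, 4 lists were over-represented in pgEpiSC, and fibroblast surface genes became over-represented in pEF (odds ratio 3.56, adjusted p = 0.0347). Acetylated length was higher in pgEpiSC at 1150 genes and in pEF at 2692. The log2 fold change turned at 14 named genes that passed the threshold in at least 1 of the 2 fits. It passed the threshold in the new direction at MYMK (-1.26), ZNRF3 (-1.14) and SPRED2 (-1.51), and did not at DAZL (-0.53), TCF12 (-0.64), FLT1 (-0.81), PECAM1 (-1.99), TIE1 (-0.062), CSF1R (-0.50), ITGB2 (-0.51), SOX6 (-0.79), ALPL (-0.16), HSP90AB1 (-0.15) and AKR1D1 (-0.23).

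With gene-end windows of 1 and 5 kb the share at gene ends was 10.5% and 17.1% of pgEpiSC-only, 7.77% and 14.6% of pEF-only and 50.97% and 55.6% of common regions. At 5 kb, 2 lists were over-represented in each type. Keeping gene-end islands gave 337 stitched domains specific to pgEpiSC. With flanks of 50 kb the log2 fold change at KLF6 was 0.63. Centring placed 3852 genes higher in pEF. In the common regions, 77 and 67 passed among those covered to 80% in every library, of which there were 409. Limma on the ratio of ChIP to scaled input gave 44 regions higher in pgEpiSC and 16464 higher in pEF, and 2562 and 1535 when centred. Without centring, where most regions were higher in pEF, it turned the log2 fold change at TRIM71 (-0.041), CLYBL (-0.13) and FGD4 with BICD1 (-0.81), and centred it gave 1.34, 1.25 and 0.58.

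When a library is left out, the lone library of its type is assumed to vary like the other type. Leaving out each library in turn gave 24023 to 34766 regions specific to pgEpiSC, the highest without pgEpiSC 1, with 10.8% to 12.6% of pgEpiSC-only, 8.22% to 10.3% of pEF-only and 48.4% to 49.6% of common regions at gene ends. The odds ratio of position lay between 1.06 and 1.61, and the lowest, without pgEpiSC 4, did not pass. Stitched domains numbered 164 to 586 in pgEpiSC, the highest without pgEpiSC 1, and 315 to 902 in pEF, the highest without pEF 1. Acetylated length was higher in pgEpiSC at 1686 to 2188 genes and in pEF at 548 to 828, and read counts at 1917 to 5157 and 2041 to 5032 regions, the lowest without a pgEpiSC library.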

Other observations

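The gene families, the test of weak islands as the source of the larger coverage, the share of extra coverage in common regions, the filter of 2-fold enrichment, the comparison of markers with the other pgEpiSC-only genes, the share of markers with an end island and the test of X copy number were chosen after the results were seen; the tests of Y and of net ChIP reads on X followed the X copy result but were set before their own values.

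Gene families, grouped by the letters of their symbols, gave 4 results past the threshold among 248 tests of 124 families (Fisher's exact test over genes, two-sided, adjusted). POU genes had an end island in pgEpiSC only at 6 of 15 (odds ratio 8.49, adjusted p = 0.0348). Among them were POU3F1, POU3F3, POU1F1, POU2F2 and POU2AF1, which encodes a coactivator rather than a POU factor. POU2AF1 had 25.4 ± 4.24 kb (SD, n = 2) in pgEpiSC and no island in pEF, and POU2F2 did not pass limma, at 9.67 ± 1.27 kb against 7.77 ± 1.41 kb. Solute carriers had one in pgEpiSC only at 46 of 350 (odds ratio 1.96, adjusted p = 0.0252), among them SLC24A2, an ion exchanger gene, with 133 ± 26.2 kb against 9.10 ± 3.25 kb, and SLC45A4 with 63.97 ± 1.98 kb and no island in pEF. Collagen genes had one in pEF only at 8 of 43 (odds ratio 4.92, adjusted p = 0.0348), which beside COL1A2, COL3A1 and COL6A3 were COL4A5, COL5A3, COL9A2, COL10A1 and COL24A1. Zinc finger genes named ZNF had one in pgEpiSC only less often than other genes, at 5 of 254 (odds ratio 0.252, adjusted p = 0.0284), and 214 of them had an end island in all 4 libraries.

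More of the genome was covered by islands in pgEpiSC (411 Mb) than in pEF (274 Mb), a ratio of 1.502. Regions called in all 4 libraries held less than the larger part: 33.5% of the extra 137.5 Mb lay in them, and 29.9% to 37.3% did over the 4 pairs of libraries. Regions that both types shared in fewer than 4 libraries were left out of this share, so it does not cover all shared sites. Among islands of at least 2-fold enrichment the ratio was 0.658, but 32.4% of pgEpiSC and 85.1% of pEF islands reached 2-fold, so this value restates the difference in enrichment and decides nothing about weakly enriched islands as the origin. Whether the lower enrichment came from the immunoprecipitation or from the cells cannot be read from these lists, and a true difference between the cell types stays open, untested.

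Markers of blood, bone and keratinocytes were over-represented among genes with end islands in pgEpiSC only, although neither label names such cells. Among islands of at least 2-fold enrichment 3 of 16 such genes (18.8%), LCP1, BGLAP and ITGB4, kept the call, against 18 of 22 (81.8%) of the pluripotency, formative and epithelial genes (Fisher's exact p = 1.91e-04) but 306 of the 1175 other pgEpiSC-only genes (26.04%, Fisher's exact p = 0.774), so weak islands were not shown to set these markers apart. Cells of these types in the cultures were not excluded, as 68.4% of the 38 measured markers had an end island in both pgEpiSC libraries, against 77.8% of all genes, and a small share of such cells could leave weak islands at part of the markers. PTPRC, an abundant leukocyte gene, had 26.2 ± 15.9 kb in pgEpiSC and 3.0 ± 4.24 kb in pEF (SD, n = 2), did not pass limma (adjusted p = 0.131) and had an end island in pgEpiSC 4 only. No sort or gate that would remove such cells is named in the labels.

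The libraries of each type differed on the X chromosome, where input density relative to autosomes was 0.574 (95% bootstrap interval over regions 0.564 to 0.585) in pgEpiSC 1 and 0.525 (0.514 to 0.541) in pEF 1, against 0.941 in pgEpiSC 4 and 0.897 in pEF 2, while the autosomes lay between 0.946 and 1.07. This is consistent with 1 X copy in pgEpiSC 1 and pEF 1 and 2 copies in the others, and the start of X, which X and Y share, suggests a Y chromosome in the former: over the first 6 Mb the density was 0.949 and 0.936, and past 8 Mb it was 0.550 and 0.515, although no island lay on Y in any library. Net ChIP reads in islands on X relative to autosomes were 1.11 times (1.04 to 1.18) as high in pgEpiSC 4 as in pgEpiSC 1 and 1.05 times (0.988 to 1.11) as high in pEF 2 as in pEF 1, where the autosomes ranged from 0.685 to 1.05 and from 0.924 to 1.097. Both ratios lay under 1.3, the limit set beforehand for the case that not both X copies were acetylated in pgEpiSC 4 and pEF 2. A higher limit had been set for acetylation of both. The medians over regions were 0.895 and 0.985. These limits left out that reads were counted in each library's own islands. They also left out that the intervals cover regions and not libraries, with 1 library on each side. Single autosomes ranged by more than 1.3 times in pgEpiSC, so the question stayed open.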
